A study of Oryza sativa Japonica Group with 4 samples.

How the data were processed

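Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was applied to seedlings of Nipponbare, a japonica rice cultivar. Seeds were germinated for 72 h and plants were sampled at 2 weeks; the material was mainly leaf. Per the labels, 4 libraries were made. A pan anti-crotonyllysine antibody (Kcr), which is raised against crotonylated lysine in any protein, was used for 2 of them. An antibody against crotonylation of lysine 14 of histone H3 (H3K14cr) was used for the other 2. The labels' protocols also describe a mock precipitation with normal rabbit serum; its data are not analysed here. The libraries were sequenced on an Illumina HiSeq instrument, per the labels' protocols, and aligned with Bowtie, per the submitters' processing notes. The Bowtie version, the genome build, the peak caller, its threshold and the use made of the mock sample are not given in the sources used here.

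The deposited files are 2 lists of enriched regions, 1 per mark. Each has 3 columns, namely the chromosome, the start and the end of a region in base pairs, on chromosomes 1 to 12. The labels name each list as the file of both replicates of its mark. Whether the authors called regions on pooled reads, or kept regions called in both replicates, is not given in the sources used here. The lists as used here carry no score, fold enrichment or p-value per region and no read number. The sequencing depth behind each region is therefore unknown, and no spread between replicates could be computed. Every p-value below compares positions or widths of regions within and between these 2 lists. It does not measure biological variation.

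Positions are printed as deposited. Whether starts were counted from 0 or 1 is unknown, so a position may be off by 1 bp. No region of one list only touched the boundary of a region of the other (0 cases), so this had no effect on the overlaps. Width was taken as end minus start. Chromosome lengths were approximated by the last region end in either list, which gave a span of 373.0 Mb over 12 chromosomes. The gene table at hand belongs to an assembly that could not be matched to the build of the lists. Genes, promoters, transcription start sites and the gene lists fixed in advance (22 lists) were therefore not analysed here, and regions are named by position. The planned score of a region was replaced by its width, as provided for in the plan. The regions named are the 3 widest shared regions (ranked by their Kcr width), the 3 widest of each mark alone and, chosen after their values were seen, the extremes of density, the longest gaps and 2 clusters of wide regions.

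A region was called shared when it overlapped a region of the other list by at least 1 bp. Chance was estimated from 10000 circular shifts, in which all Kcr regions of a chromosome were displaced by 1 random distance and wrapped around its end, so that widths and spacing were kept. The p-value is one-sided and the smallest it can be is 0.0001. Alternatives used 1000 displacements, or 100 for overlap fractions. The Jaccard index is the number of bases in both lists over the number in either. Median widths of shared and unshared regions were compared with two-sided permutation tests of 100000 resamples, and standard errors came from 1000 bootstrap samples. Densities were counted from region midpoints in 1 Mb windows. They were compared by Spearman's rho with 10000 random rotations of the windows within each chromosome. The order of the chromosomes was also shuffled, so windows of different chromosomes were set against each other. Unevenness was expressed as the squared coefficient of variation over windows after subtraction of the part due to counting, with intervals from 10000 bootstrap samples of windows. Neighbouring windows are not independent, so these intervals are too narrow. The permutation tests of chromosome ends take windows as exchangeable, so their p-values may be too small. A family of 19 tests was counted, which takes in the widths relative to the window but no other alternative setting; after Benjamini-Hochberg adjustment 17 had an adjusted p of at most 0.0022, and the other 2 (H3K14cr at chromosome ends and clusters of wide H3K14cr regions) had 0.19 and 0.063. Shares carry 95% Wilson intervals, which cover counting error only.

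Alternatives fixed before the data were examined were an overlap of 50% of the Kcr region, 50% reciprocal overlap, restriction to the wider 50% of each list, uniform random placement, merging of regions up to 200 bp apart and 500 kb windows. Local shifts of 20 to 200 kb, widths relative to the 1 Mb window, covered bases, the analysis of edges and nesting, the unevenness along chromosomes, chromosome ends and wide clusters were added after the data had been seen.

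The procedures were tested on simulated data. With the Kcr list displaced at random, 5 of 100 simulated lists had an overlap p-value under 0.05. These lists were made by the same circular shifts that the test uses, so this checks the calculation of the p-value only. With H3K14cr widths shuffled as well, 4 of 100 had a width p-value under 0.05. Shuffling removes any link between width and overlap, so this checks the permutation step only. With real widths and shifted Kcr lists, the H3K14cr width difference ranged from 158 to 410 bp over 1000 shifts. The width p-value therefore does not allow for geometry. Planted overlap shares of 20.0%, 50.0% and 80.0% of 10923 Kcr regions were recovered as 20.0%, 50.0% and 80.0%. Planted regions were centred on H3K14cr regions and the others placed clear of them, so this checks the counting only. A planted width difference of 100 bp in the H3K14cr list was recovered as 106 bp. Calculations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures were drawn with Matplotlib 3.10.9.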

Results

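The genomic distribution of lysine crotonylation, a short-chain acyl modification of histones and other proteins, was examined in rice seedlings with a pan-Kcr antibody. A second antibody, against H3K14cr, was used to check the genome-wide pattern. The specificity of the antibodies was not tested here. Each mark was profiled in 2 replicate libraries, and 1 list of enriched regions per mark was compared. The read depth is unknown and no value per replicate was at hand, so differences between the marks have no replicate check.

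Kcr occupied 10923 regions and H3K14cr occupied 18813 regions on the 12 chromosomes. The Kcr regions covered 14.66 Mb, or 3.93% of the 373.0 Mb spanned by the lists. The H3K14cr regions covered 35.64 Mb, or 9.55%. H3K14cr regions were also wider, with a median of 1621 bp (interquartile range 1202 to 2297 bp), against 1205 bp (1019 to 1514 bp) for Kcr. Regions wider than 2000 bp made up 33.8% of the H3K14cr list (6368 regions) and 9.4% of the Kcr list (1028 regions). The widest region was 7023 bp for Kcr and 8021 bp for H3K14cr. The median gap between neighbouring regions was 19259 bp for Kcr and 11583 bp for H3K14cr.

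The next comparison asked how far the pan-Kcr pattern was found with the H3K14cr antibody. Of the Kcr regions, 6983 overlapped an H3K14cr region, a share of 63.93% (95% Wilson interval 63.02 to 64.82%). Randomly shifted Kcr regions did so in 16.30% ± 0.41 of cases (SD over 10000 shifts), so the observed share was 3.92 times the chance level. No shift reached the observed share, the highest being 22.03% (one-sided permutation p = 0.0001, the smallest the shifts can give). The ratio was 6.62 where 50% of the Kcr region had to be covered and 11.9 with 50% reciprocal overlap. Each of these settings used 100 shifts (one-sided permutation p = 0.0099, the smallest that 100 shifts can give). Seen from the other list, 6981 H3K14cr regions, or 37.11% (36.42 to 37.80%), overlapped Kcr, against 9.51% ± 0.24 by chance (one-sided permutation p = 0.0001). The lists thus also held 3940 regions with Kcr alone and 11832 regions with H3K14cr alone. In bases, 9.19 Mb lay in both lists, which is 62.7% of the Kcr bases and 25.8% of the H3K14cr bases. The Jaccard index of 0.224 was 7.65 times the chance value of 0.0292 (one-sided permutation p = 0.0001); in the wider 50% of each list it was 0.144, or 7.66 times chance. Chance levels estimated from shifts of at most 200 kb, which keep the density of each part of a chromosome, were little higher, at 17.23% of Kcr regions. All these chance levels come from random positions. The excess therefore cannot tell a link between the marks from a common placement relative to genes or a common background. Neither genes nor the mock sample were used here.

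The overlap was found on each of the 12 chromosomes. The share of Kcr regions that overlapped H3K14cr ranged from 59.46% (56.13 to 62.71%) on chromosome 7 to 68.27% (64.45 to 71.86%) on chromosome 10. The share of H3K14cr regions that overlapped Kcr ranged from 33.54% (31.39 to 35.75%) on chromosome 4 to 39.76% (37.62 to 41.95%) on chromosome 2. Kcr density on these chromosomes was 25.9 and 34.1 regions per Mb. Chance overlap depends on the density of the other list, and no chance level was computed per chromosome. The ranges therefore do not show that agreement between the marks differed between chromosomes.

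Shared Kcr regions were wider than those with Kcr alone, and shared H3K14cr regions were narrower than those with H3K14cr alone. The median width of Kcr regions was 1279 bp when shared and 1099 bp when not, a difference of 180 bp (bootstrap SE 8.0, interval 164 to 195 bp; two-sided permutation p = 1e-05, the smallest it can be). For H3K14cr the medians were 1493 bp when shared and 1701 bp when not, a difference of -208 bp (SE 15.7, interval -243 to -181 bp; two-sided permutation p = 1e-05). With 50% reciprocal overlap it was -358.5 bp, but that criterion by itself bars H3K14cr regions much wider than their Kcr partner from counting as shared. Both permutation tests take sharing as unrelated to width, though wider regions meet more regions by geometry alone. With the other list shifted, the difference was 61.2 bp on average for Kcr (20 to 103 bp) and 265.1 bp for H3K14cr (158 to 410 bp). Among the narrowest 10% of Kcr regions (355 to 893 bp) 42.56% (39.67 to 45.50%) overlapped H3K14cr, and among the widest 10% (1963 to 7023 bp) 83.81% (81.50 to 85.87%) did. In the H3K14cr list the share was 44.24% (42.02 to 46.49%) in the narrowest 10% (427 to 1035 bp) and 30.62% (28.58 to 32.74%) in the widest (3154 to 8021 bp).

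**Figure D1:**
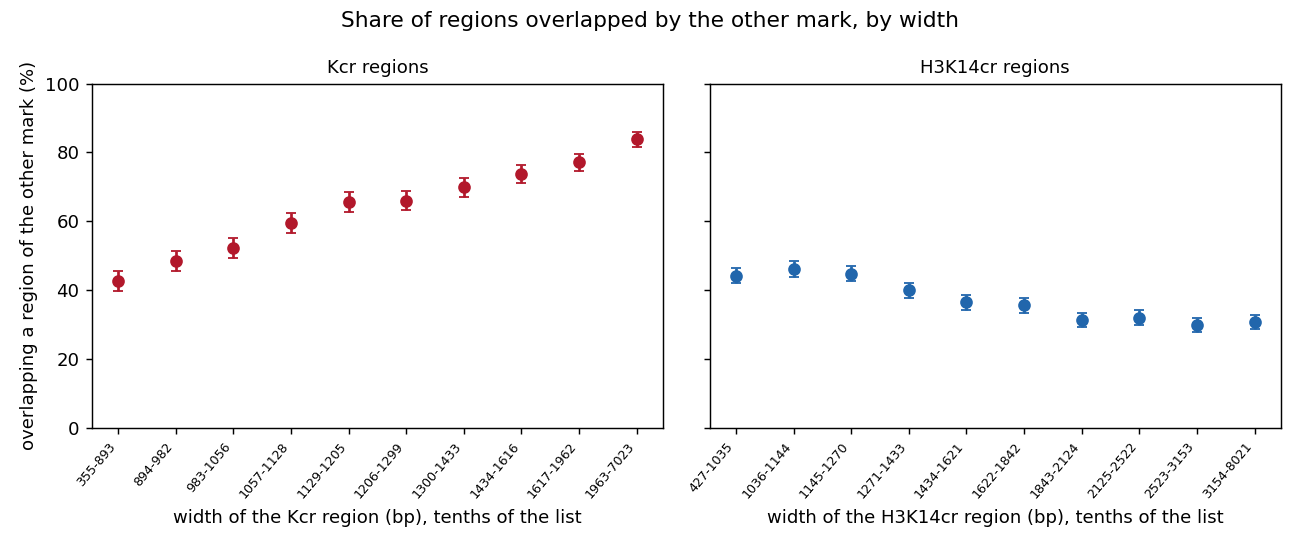
Share of regions (%, y axis) that overlap a region of the other mark by at least 1 bp, for 10 equal parts of each list ordered by region width (bp, x axis); points are shares and bars 95% Wilson intervals. The share of Kcr regions goes from 42.56% in the narrowest to 83.81% in the widest part, and that of H3K14cr regions from 44.24% to 30.62%. No chance level is drawn, and wider regions meet more regions by geometry alone.

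Where the marks overlapped, the borders of their regions lay close together. Among 7027 overlapping pairs, the nearer of the pair of edges differed by a median of 51 bp and the farther by 208 bp. Both edges agreed within 100 bp in 1753 pairs, or 24.95% (23.95 to 25.97%). In 1011 pairs, or 14.39% (13.59 to 15.23%), one edge agreed within 100 bp while the other differed by more than 500 bp. The H3K14cr region was the wider by a median factor of 1.10, and widths of paired regions were correlated across pairs (Spearman's rho 0.54, two-sided permutation p = 0.0001; pairs are not independent replicates). A Kcr region lay wholly inside its H3K14cr region in 2781 pairs (39.58%), and an H3K14cr region wholly inside its Kcr region in 1055 pairs (15.01%).

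Nested Kcr regions tended to sit against one border of the H3K14cr region. This was measured in the 1244 nested pairs in which the H3K14cr region was at least 500 bp the wider. The Kcr region lay in the outermost 10% of the available room at either end in 547 of them, or 43.97% (41.24 to 46.74%), where uniform placement gives 20% (exact binomial test, two-sided p = 2e-81). The lower-coordinate edge was taken in 254 pairs and the higher-coordinate edge in 293. The middle 20% of the room held 114 pairs, or 9.16% (7.68 to 10.90%).

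**Figure D2:**
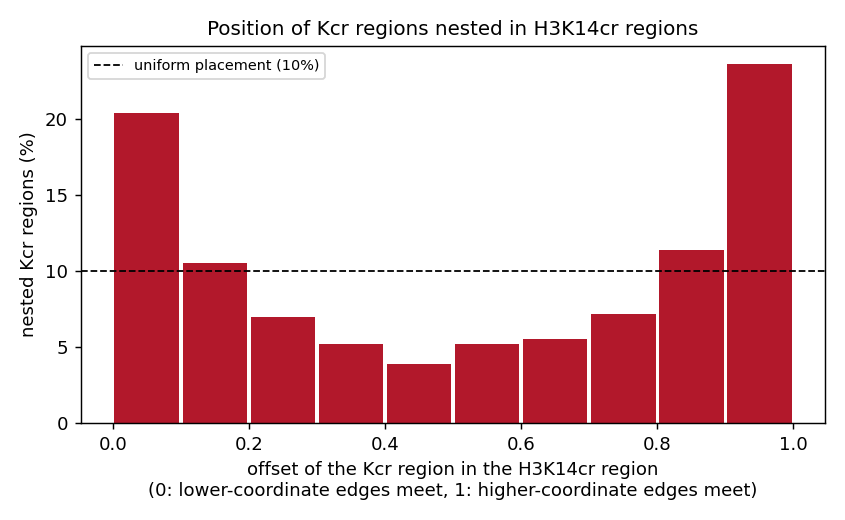
Offset of Kcr regions nested in an H3K14cr region at least 500 bp wider (x axis, 0 where the lower-coordinate edges meet and 1 where the higher-coordinate edges meet) against the share of the 1244 nested regions (%, y axis). Bars are 10 equal parts of the available room and the dashed line marks uniform placement; the outermost bars reach 20.4% and 23.6%, and the lowest bar is 3.9%.

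Over the genome as a whole, the densities of both marks varied together. Over 379 windows of 1 Mb, of which 12 were the shorter last windows of the chromosomes, the numbers of Kcr and H3K14cr regions were correlated with Spearman's rho of 0.71 and Pearson's r of 0.70 (two-sided permutation p = 0.0001). The highest rho over 10000 rotations with shuffled chromosome order was 0.33. Density differences between whole chromosomes thus also count towards this p-value. In the 367 full windows rho was also 0.71. Within single chromosomes rho ranged from 0.19 on chromosome 12 to 0.84 on chromosome 4, and without the outer 2 Mb of each chromosome it was -0.01 on chromosome 12. A full window held a median of 28 Kcr regions (range 7 to 65) and 50 H3K14cr regions (range 15 to 85). The most Kcr regions, 65, lay between 35000001 and 36000000 on chromosome 3, beside 61 H3K14cr regions. The most H3K14cr regions, 85, lay between 33000001 and 34000000 on chromosome 1, beside 47 Kcr regions. The fewest Kcr regions, 7 per window, were found on chromosome 4 at 3000001 to 4000000 and at 10000001 to 11000000, where H3K14cr had 34 and 24 regions.

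Kcr was spread less evenly than H3K14cr. Beyond counting error, the coefficient of variation over 367 full windows was 29.7% for Kcr and 19.3% for H3K14cr. The ratio of the squared coefficients was 2.37 (bootstrap interval 1.88 to 3.04), and it stayed between 2.15 and 2.49 when each chromosome was left out in turn. Chromosome ends were on average rich in Kcr. The first and last full windows of the chromosomes held 41.6 ± 10.6 Kcr regions (SD, n = 24 windows) and the remaining windows 28.0 ± 9.5 (n = 343 windows), a ratio of 1.49 (two-sided permutation p = 1e-05). For H3K14cr the corresponding numbers were 53.3 ± 8.1 and 50.01 ± 12.2, a ratio of 1.07 (two-sided permutation p = 0.19). Kcr made up 43.81% (41.79 to 45.86%) of all regions in the end windows and 35.86% (35.29 to 36.44%) elsewhere, a difference of 7.95 percentage points (two-sided permutation p = 1e-05). Not every end was rich, since the first windows of chromosomes 9 and 10 held 24 and 20 Kcr regions. Each other end window held at least 30. The lowest of these, 30 in the last full windows of chromosomes 11 and 12, lay near the mean of the remaining windows. Some others also lay within the SD of that mean. The shorter windows beyond the last full ones were left out.

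**Figure D3:**
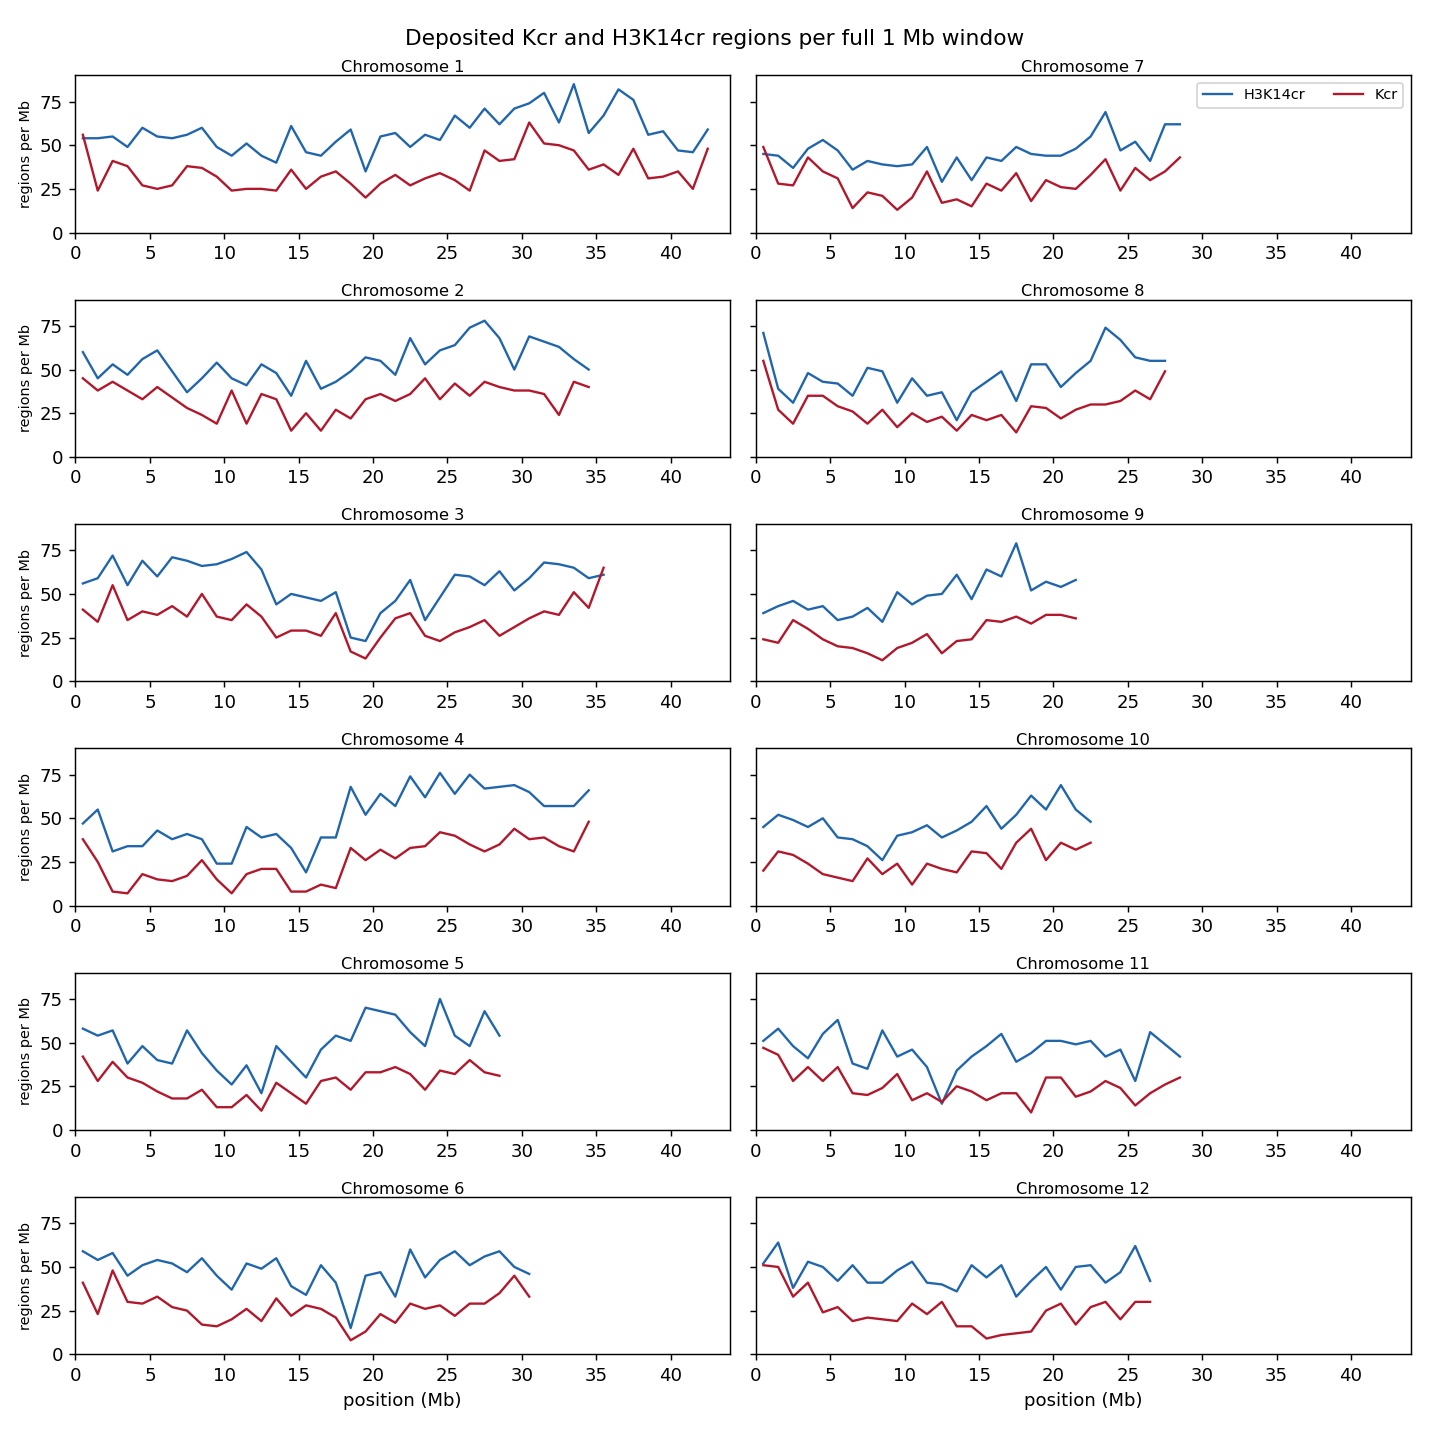
Number of deposited regions per full 1 Mb window (y axis) along each of the 12 chromosomes (x axis, Mb) for Kcr (red) and H3K14cr (blue). On chromosome 4 the first 18 windows average 16.0 Kcr and 36.9 H3K14cr regions and the following 17 average 35.4 and 64.6. That border was placed where the Kcr contrast was largest. End windows of all chromosomes average 41.6 Kcr regions against 28.0 in the others.

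The widest shared region lay on chromosome 9, where Kcr spanned 4691057 to 4697808 (6751 bp) and H3K14cr 4691057 to 4697866 (6809 bp). The next was 28.1 kb away on the same chromosome, with Kcr at 4725924 to 4732665 (6741 bp) and H3K14cr at 4725905 to 4732740 (6835 bp). The third lay on chromosome 1, where Kcr spanned 33516053 to 33522642 (6589 bp) and overlapped an H3K14cr region at 33518640 to 33522725 by 4002 bp. The 3 widest regions with Kcr alone lay together on chromosome 12, at 20654455 to 20661478 (7023 bp), 20627733 to 20634140 (6407 bp) and 20618059 to 20623656 (5597 bp). The 3 widest with H3K14cr alone were on different chromosomes, at 4803223 to 4810900 on chromosome 12 (7677 bp), 17341107 to 17348479 on chromosome 4 (7372 bp) and 5907874 to 5915200 on chromosome 5 (7326 bp).

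**Figure D4:**
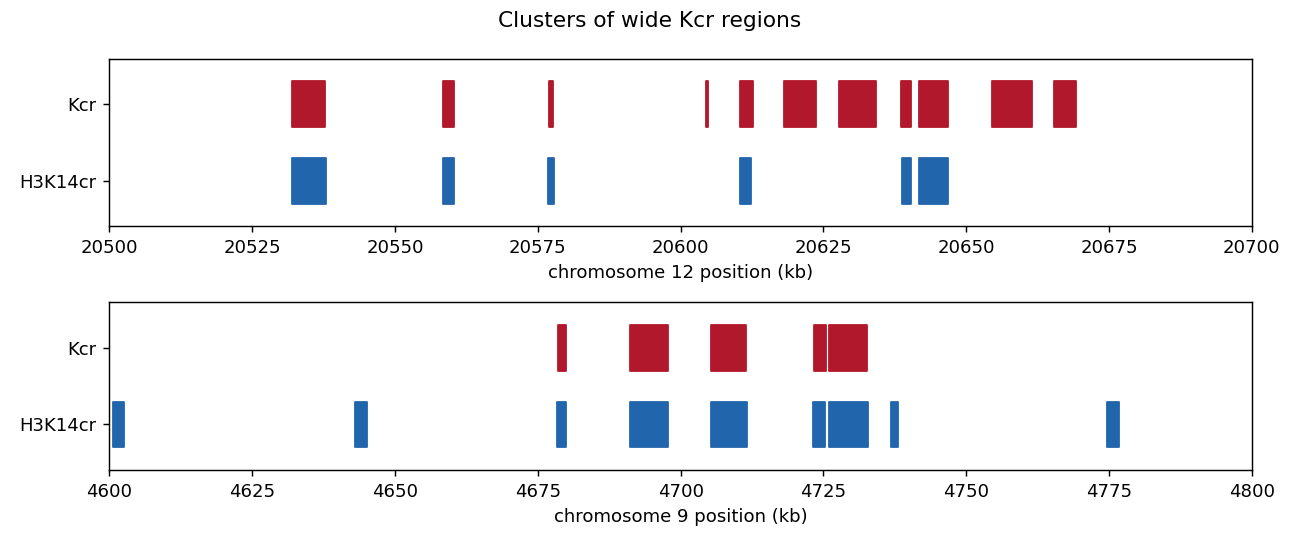
Kcr (red) and H3K14cr (blue) regions drawn to scale in a 200 kb part of chromosome 12 and of chromosome 9 (x axis, position in kb). On chromosome 12 Kcr regions of 5597, 6407 and 7023 bp have no H3K14cr counterpart, while those of 5861 and 5105 bp have one of nearly the same extent. On chromosome 9 the Kcr regions of 6751, 6114 and 6741 bp each have an H3K14cr region of nearly the same extent.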

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

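The comparison with shifted lists was chosen after the result it bears on was seen; the adjustment for the 1 Mb window was chosen before its own value was known. The relation between width and sharing had opposite signs in the 2 lists. Shared minus unshared median width was 180 bp for Kcr and -208 bp for H3K14cr, and the difference between these, 388 bp, was larger than in any of 10000 permutations of the shared label (two-sided permutation p = 0.0001). Wider regions meet more regions of another list by geometry alone, and with shifted Kcr lists the H3K14cr difference was 265.1 bp on average, ranging from 158 to 410 bp over 1000 shifts, which excludes geometry as the source of the observed -208 bp. For Kcr the shifts gave 61.2 bp (20 to 103 bp), so geometry accounts for at most part of the 180 bp. After subtraction of the median width of the 1 Mb window, the H3K14cr difference was still -151 bp (two-sided permutation p = 0.0001). This argues against location in different 1 Mb windows as the whole source. Location at a finer scale, such as relative to genes, was not tested. It remains open whether the wide H3K14cr regions carry too little crotonylation in total to be called with the pan antibody, or whether the depth or threshold of the Kcr list missed broad, low signal; without read numbers neither was tested.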

How the results depend on the processing

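No paired analysis was possible because each mark has 1 list for both replicates, and leaving out a replicate was not possible for the same reason. The local shifts, the widths relative to the window, the merged lists other than for overlap, the full windows only, the windows without chromosome ends and every alternative for nesting and unevenness were chosen after seeing the data. All 25 alternatives run on the 11 results compared kept the direction and the side of the threshold, or lay within 1.5 times the value for counts and widths. The share of shared Kcr regions was 62.95% with 50% of the Kcr region covered (chance 9.51%), 55.80% with 50% reciprocal overlap (chance 4.69%), 63.87% after merging and 42.74% in the wider 50% of each list (chance 10.98%). The Jaccard index was 0.144 in the wider 50% of the lists, where the chance value was 0.0188. The width difference of H3K14cr was -151 bp relative to the window, -208 bp after merging and -358.5 bp with 50% reciprocal overlap, a criterion that by itself keeps H3K14cr regions much wider than their Kcr partner from counting as shared. The width difference of Kcr ranged from 158 to 183 bp. Spearman's rho between the marks was 0.63 in 500 kb windows, 0.71 in full windows only and 0.73 without the outer 2 Mb, where single chromosomes ranged from -0.01 (chromosome 12) to 0.88 (chromosome 4). The ratio of squared coefficients of variation ranged from 1.93 to 2.79. The alternatives that need genes or organelle sequences (placement within genes, windows around start sites, promoter sizes, gene bodies, removal of organelle-like regions) were not run. The unknown read depth limits statements about regions found with 1 antibody only, since absence from a list cannot be told from a signal below its threshold.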

Other observations

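The tests in this part were chosen after the patterns had been seen, except for the distance of Kcr-only regions, covered bases and the windows without chromosome ends, whose values were not known when they were chosen. Some of the widest Kcr regions lay near each other. Of the 110 Kcr regions wider than 3223 bp (the widest 1%), 24 had another of them within 50 kb, where shuffled widths gave 3.6 on average and at most 18 (one-sided permutation p = 0.0001). Among the 189 H3K14cr regions wider than 5139 bp the number was 17, against 9.9 for shuffled widths (one-sided permutation p = 0.06). The 24 Kcr regions include some of the clusters already seen on chromosomes 12 and 9. The test was not repeated without those clusters, so it does not show clustering elsewhere. The cluster on chromosome 12 held 5 Kcr regions wider than 5000 bp between 20531920 and 20661478, of which 2 had an H3K14cr region with nearly the same borders (20531919 to 20537833 and 20641837 to 20646894) and 3 had none. On chromosome 4 the first 18 full windows, a border placed where the Kcr contrast was largest, held 16.0 ± 8.2 Kcr regions each (SD) and the following 17 windows 35.4 ± 5.8, a ratio of 2.21, while H3K14cr had 36.9 ± 8.8 and 64.6 ± 7.0, a ratio of 1.75. This choice of border favours a larger ratio for Kcr, so the ratios do not compare the marks on equal terms.

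Nested Kcr regions lay at an edge of the wider H3K14cr region in 43.97% of cases, beyond the 20% of uniform placement. H3K14cr regions that overlap 2 Kcr regions, each at its own edge, are too few to be the whole source, since they hold 57 nested pairs, against an excess of 298 pairs at the edges over uniform placement (264 to 333). With at least 1000 bp of room it was 47.79%. A candidate explanation is that both marks start at a common border, such as a transcription start, and extend to different lengths. This hypothesis was not tested, since strand and gene positions were not used here.

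Kcr varied more than H3K14cr from window to window, with a ratio of squared coefficients of variation of 2.37. With covered bases in place of region numbers the ratio was 2.00 (1.72 to 2.35), which argues against an effect of counting regions. Without the outer 2 Mb of each chromosome it was 1.93 (1.52 to 2.45), so chromosome ends are not the whole source. At the ends Kcr made up 43.81% of all regions, against 35.86% elsewhere, a difference of 7.95 percentage points in the same direction on 12 of 12 chromosomes (two-sided permutation p = 1e-05). A difference in depth or threshold between the lists and a biological difference between the marks both remain open, and neither was tested.

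The distance from regions with Kcr alone to the nearest H3K14cr region gave no excess of near neighbours within 1 kb. An H3K14cr region lay that close to 407 of the 3940, or 10.33% (9.42 to 11.32%), which was below the 11.80% of local shifts and outside their range of 10.81 to 12.77% (two-sided permutation p = 0.002, the smallest the shifts can give). The median distance, 5436 bp, lay inside the range of the shifts (5362 to 5941 bp, mean 5663 bp). The longest stretch without Kcr, 656.2 kb on chromosome 6 between 18165528 and 18821701, held 5 H3K14cr regions. H3K14cr was also sparse there, with 15 regions in the window from 18000001 to 19000000, against a median of 50 in full windows. The longest without H3K14cr, 415.4 kb on chromosome 7 between 11897789 and 12313168, held 0 Kcr regions. It lay within a stretch of 525.6 kb without Kcr, from 11894580 to 12420193. Whether reads can be aligned to these stretches was not examined.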
